A study of Escherichia coli str. K-12 substr. MG1655 with 8 samples.

How the data were processed

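H-NS-FLAG ChIP-seq and input DNA were analysed from 8 libraries of Escherichia coli K-12 MG1655, 2 each of ChIP and input from untreated and bicyclomycin-treated cells, sequenced on a HiSeq 1000 per the labels. The authors aligned 50 nt reads with BWA (version not given in the sources used here) to a single chromosome whose build is not given in the sources used here. The deposited files hold 1 line per read with its start, end, strand and a score, which in the deposited values behaves as the BWA mapping quality, from 0 to 37. These read files hold no counts, peaks or normalised values. Unaligned reads, kept in the files with a start of 0, were left out; they made up 0.433% to 1.98% of ChIP and 5.46% to 8.77% of input reads. Of the aligned reads, 96.3% to 98.5% had a mapping quality of at least 20. Distinct stranded start positions covered were 57.8%, 65.4%, 78.2% and 85.7% of those possible in the ChIP libraries (untreated 1 and 2, treated 1 and 2). The aligned reads per library, 18755024 to 27813502, leave counting error small beside the difference between replicates.

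The reference gene table follows the ASM584v2 assembly, and the coordinates of the files, which end at 4639676, could not be shown to be of that build. Genes were therefore not placed by coordinate, and windows of 1 kb replaced the genes named in the plan. Repeated sequence was located as blocks of reads with low mapping quality, and 61 of 105 blocks were matched in order to the repeats of the gene table (32 insertion elements, 14 tRNA operons, 7 ribosomal RNA operons and others). Of 60 spacings compared, 50 differed by at most 200 bp and the largest difference was 889.5 bp. The matching itself used length and spacing, allowed spacings to differ by at most 1300 bp and favoured small differences. These spacings are therefore no independent check of the match. The table was used for names and for which genes neighbour these blocks.

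Reads were assigned to windows by their midpoint. Windows with under 80% of reads at a mapping quality of at least 20 (148 windows) or with a mean under 10 reads (7 windows) were left out of 4639, which left 4484. Libraries were scaled by the median ratio to the geometric mean, and the log2 of scaled CPM plus 1 was fitted with limma 3.58.1 (group means, eBayes with trend, 4 residual degrees of freedom, 2.95 prior degrees of freedom) in R 4.3.3. The contrasts were ChIP over input in each treatment, their difference (the change), their average and treated over untreated input. The threshold was a Benjamini-Hochberg adjusted p of 0.05, two-sided, and bound windows also needed a log2 enrichment of at least 1. Sets of windows were tested with camera (limma), with the preset correlation of 0.01 and with an estimated one, adjusted over 10 stretches. On simulated data the change contrast recovered 11 of 50 windows changed 1.5-fold, 43 of 50 changed 2-fold and 50 of 50 changed 3-fold, with 6 calls among 4284 unchanged windows. The simulated spread of each group was taken over all windows, and replicates differed more than that in bound windows.

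Bound regions were runs of 200 bp windows at least 2-fold over the mean input in each ChIP library, joined over gaps of 1 window, of at least 2 windows. The origin to terminus gradient was a straight line through log2 input reads in 10 kb windows against the distance from the origin, whose position was estimated from the inputs. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

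The tests, the 22 gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, at most 1 per 5 kb, the 10 bound windows with the largest rise and fall past the threshold with all 4 ChIP libraries apart, filled to 5 with unbound windows, the 10 most enriched in untreated cells, and up to 4 members of each list. Applied to windows, the list part became the windows next to matched blocks on the side of a list gene that were bound or called. The lists were followed as 13 stretches of 9 lists, of which 10 held windows to test. The 1 such stretch of the CP4-44 prophage held no tested window. The members of the other lists were not analysed here as lists, apart from the windows next to matched blocks. Some of them lie in stretches followed for another list. The alternatives were total-read scaling, quantile normalisation, pseudocounts of 0.1 and 5, no filters, voom weights, mapping quality of at least 20, at most 10 reads per position, 5-prime ends, replicate blocks, ChIP libraries alone, other thresholds and leaving out each library. Leaving out 1 library leaves a group of 1, which is assumed to vary like the other groups. Added after seeing the data were windows shifted by 500 bp, windows of 2 kb, a replicate block with the untreated input numbers exchanged, and leaving out both inputs with few reads in bound windows. The repeat filter by mapping quality and the use of stretches were also chosen then. Replicate numbers were not treated as pairs, since the labels do not say that equal numbers share a culture.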

Results

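H-NS, a nucleoid protein that binds AT-rich DNA and silences horizontally acquired genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Escherichia coli K-12 MG1655 carrying a FLAG tag on H-NS. Cells grew in LB at 37 °C with shaking at 200 rpm, either untreated or with 25 µg/mL bicyclomycin, an antibiotic. Untreated cells were grown to an OD600 of about 0.8, and bicyclomycin was added at an OD600 of 0.1. The OD600 at which treated cells were harvested is not given in the sources used here. The 8 libraries formed 4 groups of 2: ChIP and input DNA from untreated cells, and ChIP and input DNA from treated cells. The labels call the replicates biological duplicates. ChIP replicates 1 and 2 held 20556519 and 21614869 aligned reads in untreated cells and 24165476 and 27813502 in treated cells. Input replicates 1 and 2 held 21121241 and 18755024 in untreated cells and 21766479 and 20162813 in treated cells. Positions are those of the deposited read files, whose genome build is not named, on the single chromosome. Gene names are given only where a window lies beside a repeat, such as a tRNA operon or an insertion element, that could be recognised in the reads. The study asked how H-NS occupancy compares between cells with and without bicyclomycin.

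H-NS bound many short regions and a few long ones in untreated cells, with a median length of 0.8 kb and 6 regions of at least 10 kb, and most of the windows bound there were bound after bicyclomycin. Of 4484 windows of 1 kb tested, 1061 were bound in untreated cells and 906 in treated cells, with 837 bound in both. Among the most enriched windows beside a recognised repeat were those next to ygeO, a gene of the type III secretion remnant ETT2, and next to wbbK, an O-antigen synthesis gene. The window at 2993001 on the ygeO side of insD4-insC4 reached a log2 enrichment of 7.13 ± 0.44 (SD, n = 2) in untreated cells and 5.14 ± 0.80 (SD, n = 2) in treated cells. The window at 2101001 on the wbbK side of insH7 was 115-fold over input in untreated and 27.9-fold in treated cells. The highest enrichment of all, 7.55 in untreated and 5.70 in treated cells, was at 4474001, between the glyV-glyX-glyY tRNA genes and insC6-insD6. The windows at 1211001, 2467001, 2988001, 4280001, 3795001, 3802001 and 583001 completed the 10 most enriched, with untreated values from 6.89 to 7.49. All 10 had lower values in treated cells, by a log2 change of -1.81 at 583001 to -2.46 at 3795001. None of these 10 differences passed the limma test of the change, with adjusted p from 0.224 to 0.449. All 10 passed with the ChIP libraries alone and 3 each with quantile normalisation and scaling by total reads. With a replicate block in which the numbers of the untreated inputs were exchanged, 9 passed. That exchange was chosen from the replicate differences in these data. In 1 kb windows the smallest adjusted p for enrichment was 0.000294 in untreated and 0.000623 in treated cells. With libraries scaled by total reads, 654 windows were bound in untreated cells.

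**Figure D1:**
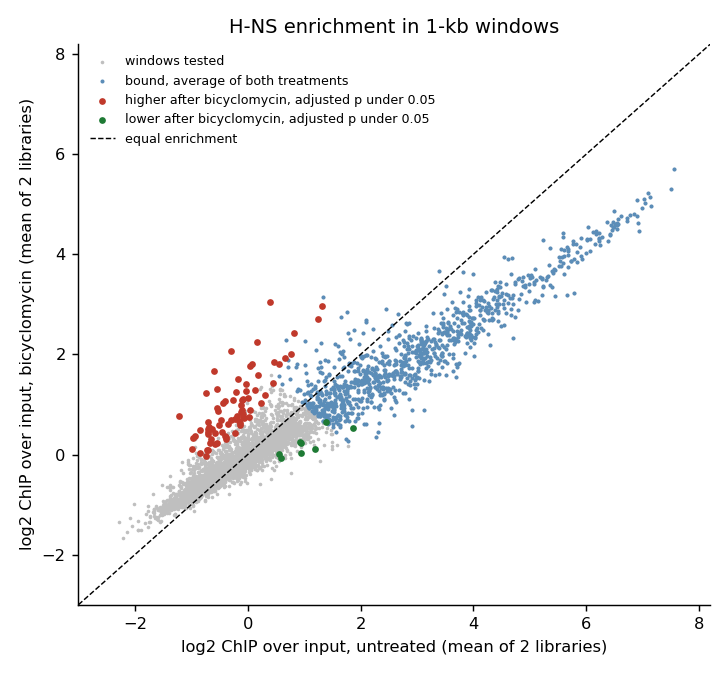
Each point is a 1 kb window, with the log2 ratio of ChIP to input in untreated cells (mean of 2 libraries) on the x axis and in bicyclomycin-treated cells on the y axis, and the dashed line marks equal enrichment. Windows with high enrichment lie below the line, with a maximum of 7.55 untreated against 5.70 treated, and the 74 windows that rose lie above it at low untreated enrichment.

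Bicyclomycin-treated cells had lower H-NS enrichment across most bound windows. Over the 983 windows bound in the average of both treatments, the median log2 enrichment was 2.73 in untreated and 1.86 in treated cells, and the median change was -0.95. The per-library medians were 2.97 and 2.51 in untreated replicates 1 and 2 and 2.13 and 1.61 in treated replicates 1 and 2. In 801 of the 983 windows both treated ChIP libraries lay below both untreated ones, and in 55 both lay above. Chance gives 16.7% in each direction for a single window, but bound windows of a library move together, so this is no chance level for the counts. The 216 windows with a log2 enrichment of at least 4 in untreated cells had a median change of -1.63 (interquartile range -1.89 to -1.38), and 215 of them were lower in both treated libraries. Camera, the limma test of a set against the other windows, gave p = 1.1e-33 for the bound windows with its preset correlation of 0.01. The call was lost with an estimated correlation, p = 0.218 by the same limma function. The median change was -0.53 with scaling by total reads, where the median of all windows was 0.63, and -0.15 with quantile normalisation. Quantile normalisation gave the ChIP libraries of both treatments the same distribution, so it takes out a common fall.

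Bound windows took 64.4% ± 5.88 (SD, n = 2) of the ChIP reads in tested windows of untreated cells and 41.2% ± 7.96 (SD, n = 2) of those of treated cells. The shares of replicates 1 and 2 were 68.5% and 60.2% in untreated cells and 46.9% and 35.6% in treated cells. In input DNA the same windows, which make up 21.9% of those tested, took 13.4% ± 3.45 (SD, n = 2) of the reads from untreated and 12.8% ± 1.68 (SD, n = 2) from treated cells. The 95% Wilson interval of untreated ChIP replicate 1 ran from 68.51% to 68.55%, and such intervals cover counting error only. The shares were not tested; an exact permutation of 2 libraries against 2 cannot give a two-sided p below 0.333.

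**Figure D2:**
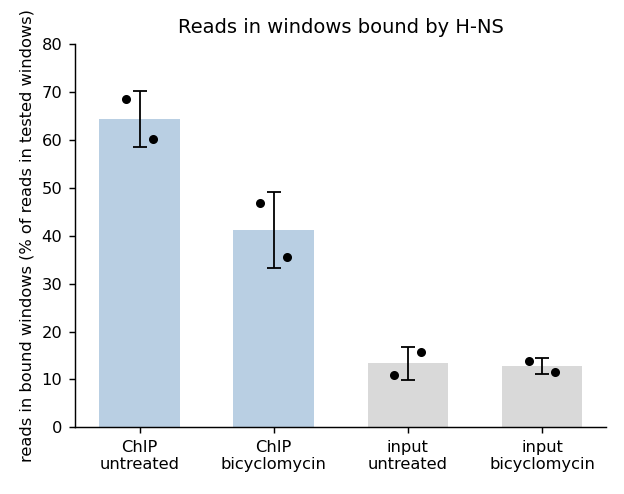
Bars give the mean percent of reads in tested windows that fell in bound windows, points the 2 libraries of each group, and error bars the SD. ChIP libraries of untreated cells lie at 68.5% and 60.2%, those of treated cells at 46.9% and 35.6%, and the inputs between 10.9% and 15.8%.

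Against this lower enrichment, H-NS occupancy rose after bicyclomycin in 74 windows, in 57 runs of adjacent windows, most of them little bound in untreated cells. The 4 largest rises lay at or beside tRNA genes and in the DLP12 prophage. At 2815001, which reaches into the argQ-argZ-argY-argV-serV tRNA operon, log2 enrichment went from 0.40 to 3.04, a 6.24-fold rise (change 2.64 ± 0.20, SE; adjusted p = 0.00677), and the next window on the yqaB side rose by 1.40 ± 0.15 (adjusted p = 0.0120). At 565001, 17 bp from insE3-insF3 on the side of renD, a DLP12 gene, enrichment rose 4.24-fold from 0.16 to 2.24 (change 2.08 ± 0.20, SE; adjusted p = 0.00815). On the yjeV side of the glyV-glyX-glyY tRNA genes, the window at 4391001 rose from -0.29 to 2.07 (adjusted p = 0.0210). At 1285001, which reaches into tyrV-tyrT, the tyrosine tRNA genes, enrichment rose from -0.59 to 1.67 (change 2.26 ± 0.15, SE; adjusted p = 0.00677), and on the tpr side the window at 1284001 rose from -0.93 to 0.37 (adjusted p = 0.0210). The next 6 rises lay far from any recognised repeat, at 3554001 (change 1.98), 3890001 (1.97), 2556001 (1.86), 3055001 (1.73), 1700001 (1.72) and 2662001 (1.69).

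Other rises in bound windows included 2058001, which lies 1291 bp from asnV on the side of nac, a regulator of nitrogen assimilation, and went from 1.24 to 2.70 (2.75-fold). The window at 3182001, 1149 bp from insC5-insD5 on the side of the fimbrial gene yqiG, went from 0.67 to 1.94 (2.41-fold). The windows at 477001, 147001, 1741001 and 1305001, far from any recognised repeat, rose by a log2 change of 1.25 to 1.64. All 74 rises had both treated ChIP libraries above both untreated ones, by 0.66 to 2.64 (median 1.14). Only 2 of the 74 windows, those at 477001 and 2058001, were bound in untreated cells, and 30 were bound in treated cells. The 6 windows listed from 3554001 to 2662001 and the tRNA windows at 4391001, 1285001, 1284001 and beside yqaB were named after their values had been seen.

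Occupancy fell after bicyclomycin in 8 windows, a number that was 922 with the replicate block in which the untreated input numbers were exchanged. That exchange was chosen from the pattern of replicate differences in these data, so the larger number is no independent support. Of the 8, the largest fall was beside gadB, the acid-resistance glutamate decarboxylase gene, on the side of gadC, the glutamate and GABA antiporter gene, 713 bp from the gadB block. There, at 1567001, log2 enrichment went from 1.86 to 0.53 (change -1.33 ± 0.23, SE; adjusted p = 0.0468). Between the tyrV-tyrT tRNA genes and insH4, the window at 1331001 fell from 1.39 to 0.65 (adjusted p = 0.0480). The other named falls were not bound in the average of both treatments: 1865001 fell from 1.20 to 0.12, 1235001 from 0.94 to 0.03 and 754001 from 0.94 to 0.24. The 3 other windows that fell, at 753001, 1493001 and 1494001 (named after their values had been seen), had changes of -0.67, -0.65 and -0.55, and all 8 had both treated ChIP libraries below both untreated ones.

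In the limma test, 90.2% of the windows called were higher, against 417 higher and 574 lower windows at an unadjusted p under 0.05. The split was 279 higher and 237 lower (54.1% higher) with quantile normalisation and 1614 higher and 72 lower with scaling by total reads. It was 725 higher and 927 lower (43.9% higher) with the ChIP libraries alone and 457 higher and 922 lower (33.1% higher) with the exchanged block. Voom weights called 0 windows, and a replicate block called 13 higher and 0 lower. Leaving out 1 library left 0 higher windows without untreated ChIP replicate 1 or treated input replicate 1, 4 without untreated ChIP replicate 2, and 16 and 22 without treated ChIP replicates 1 and 2. It left 39 without untreated input replicate 1 and 14 without treated input replicate 2. The lower windows numbered 2 without untreated ChIP replicate 2, 86 without untreated input replicate 2 and 0 without any other library. Of the 16 named windows past the threshold, 15 stayed past it without untreated input replicate 2, 9 without untreated input replicate 1, and 5 or fewer without any other library. Untreated input replicate 1 and treated input replicate 2 had the fewest reads in bound windows, 10.9% and 11.6%. Without both, 127 windows were higher and 59 lower, of which 62 and 4 were among those reported.

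**Figure D3:**
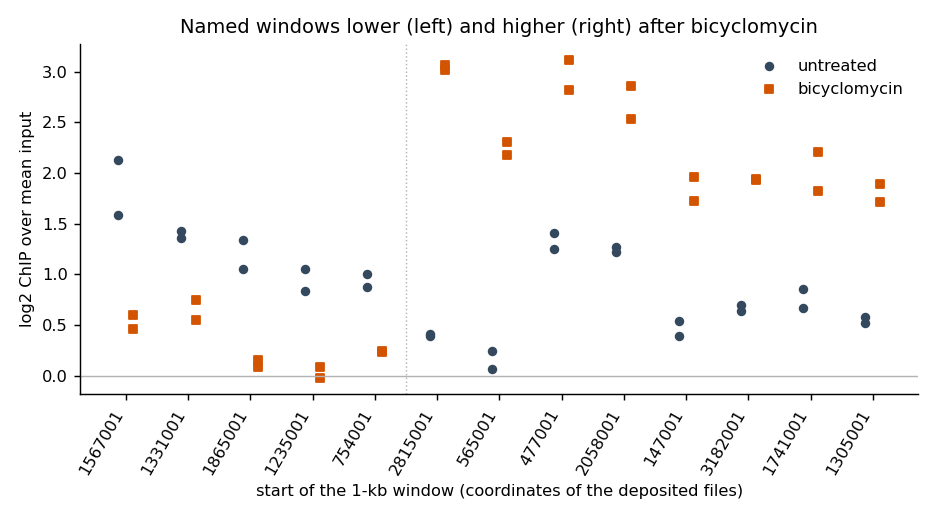
Points give the log2 ratio of each ChIP library to the mean input of its treatment in the 13 windows named by the fixed rule, 5 lower on the left and 8 higher on the right, by window start. In each window, as the rule requires, the 2 bicyclomycin libraries lie apart from the 2 untreated libraries. At 2815001 the means were 0.40 untreated and 3.04 treated.

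Genes of the fixed lists could be followed only as stretches between recognised repeats in which at least 25% of the genes belong to a list. Of 10 such stretches, none held a window that fell and only that followed for the CP4-57 prophage held windows that rose. Stretches are named by their list, but several hold mostly other genes. List genes were 24 of 94 genes in the CP4-57 stretch, 33 of 94 in Qin, 30 of 80 in Rac and 12 of 46 in ETT2. The acid-resistance island from insH11 to gadA (11 of its 14 genes are on the list, among them slp, hdeA, hdeB, gadE, mdtE and gadX) had 7 of 12 windows bound, with 0 rises and 0 falls (limma), also when adjusted over the list alone. Its median log2 enrichment was 3.26 in untreated and 2.62 in treated cells, a median change of -0.64 that turned to 0.39 with quantile normalisation. The window next to slp, an outer membrane lipoprotein gene, had 4.61 untreated and 3.19 treated, and the window next to gadX, a regulator of the acid-resistance genes, 4.32 and 3.28; both differences turned positive with quantile normalisation. The camera adjusted p of the island was 0.401, and 0.815 with an estimated correlation. With quantile normalisation it was 0.00652, in the opposite direction. As that setting takes out a common fall, its turns of sign are relative to that fall.

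The Qin stretch from gadB to insD7 had 40 of 75 windows bound and a median change of -0.52 (camera adjusted p = 4.95e-05), and the Rac stretch from insH4 to insD2-insC2-insI2 had 20 of 65 bound and a median change of -0.15 (adjusted p = 0.0434). Both calls were lost with an estimated correlation, with adjusted p = 0.815 for each. Neither stretch held a window past the limma threshold, over all windows or adjusted over the list alone. The window on the side of ydfE, a Qin gene, had 2.44 untreated and 1.63 treated. In DLP12, the 5 windows from insE3-insF3 to insH2, with emrE, a multidrug efflux gene, and nmpC, a porin gene, had a median of 4.48 untreated and 3.16 treated (adjusted p = 0.591, and 0.915 with an estimated correlation). The emrE window itself had 5.66 and 4.14, a difference that turned positive (0.14) with quantile normalisation, and the window at 572001 was higher when adjusted over the list alone (change 0.93). The DLP12 stretch from insH2 to insL2, which holds the lysis gene essD, had a median change of -0.10 over 31 windows (adjusted p = 0.384, and 0.854 with an estimated correlation). Its adjusted p was 0.0470 with the ChIP libraries alone. The window next to essD had 2.11 untreated and 1.51 treated.

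The CP4-57 stretch from the rrnG ribosomal RNA operon to argQ had 28 of 85 windows bound, a median change of -0.11 that was 0.0046 with quantile normalisation, and 2 windows that rose. These were the yqaB window named above and that at 2809001 (change 0.94), named after its value had been seen. The gene yqaB is not on the CP4-57 list, and whether 2809001 lies in the prophage was not determined. By order in the gene table the stretch also holds stpA, proV, proW and proX, which are on the list of textbook H-NS-silenced loci. Which of its bound windows cover these genes or the prophage was not determined. The adjusted p of the stretch was 0.769, and 0.916 with an estimated correlation. In CP4-6, the 3 windows from insH1 to insB2 (mmuP, mmuM, afuC and afuB) had a median of -1.05 untreated and -0.64 treated (adjusted p = 0.169, and 0.815 with an estimated correlation). The 9 windows from insB2 to insB3, with argF, an ornithine carbamoyltransferase gene, had -1.95 and -1.26 (adjusted p = 0.211, and 0.854 with an estimated correlation). Its adjusted p was 0.0413 with quantile normalisation, 0.0175 with a replicate block within treatment, 0.00295 without treated input replicate 2 and 0.00200 without both inputs with few reads in bound windows. The ETT2 stretch from metZ-metW-metV to insD4-insC4 had 13 of 48 windows bound and a median change of -0.0017 (adjusted p = 0.832, and 0.916 with an estimated correlation), whose sign turned under several settings. On the other side of insD4-insC4, the ygeP window had 3.40 untreated and 3.67 treated, and its sign turned when at most 10 reads per position were kept.

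The stretch from rrnD to tufA, followed for the ribosomal protein list, holds 61 genes. Of these, 26 are ribosomal protein genes, with rplB, rpsJ and rpsC, and 15 are of the type II secretion and chitinase list. Which of them the bound windows cover was not determined. The stretch had 7 of 41 windows bound and a median change of -0.17 (camera adjusted p = 0.0434, and 0.815 with an estimated correlation). Its call was lost with the ChIP libraries alone (adjusted p = 0.356). Among single windows beside list genes, that of chiA, a chitinase gene in the same stretch, had 2.75 untreated and 1.23 treated (limma adjusted p = 0.130). The windows of the fimbrial genes yqiG, yqiH and yhcF had 3.92, 3.70 and 1.98 untreated and 2.41, 2.84 and 1.80 treated. The differences of yqiH and yhcF turned positive with quantile normalisation, and none of the 4 passed the test. Without a library, the Rac adjusted p was 0.134 (treated ChIP replicate 2), 0.204 (untreated ChIP replicate 1), 0.280 (treated input replicate 1), 0.0816 (untreated input replicate 1) and 0.0767 (untreated input replicate 2). The ribosomal protein adjusted p was 0.0870 and 0.0688 (treated ChIP replicates 1 and 2), 0.205 (untreated ChIP replicate 2), 0.0698 (treated input replicate 1) and 0.233 (untreated input replicate 1). The Qin call held without each library. The Rac and ribosomal protein calls were also lost without the filter on repeats (adjusted p = 0.0959 and 0.0773), without that on low counts (0.0518 for both) and with scaling by total reads (0.207 and 0.379). Textbook H-NS targets such as proV, bglG, leuO, csgD and casA, and hns, stpA, flhD and tnaA, could not be placed and were not analysed here.

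**Figure D4:**
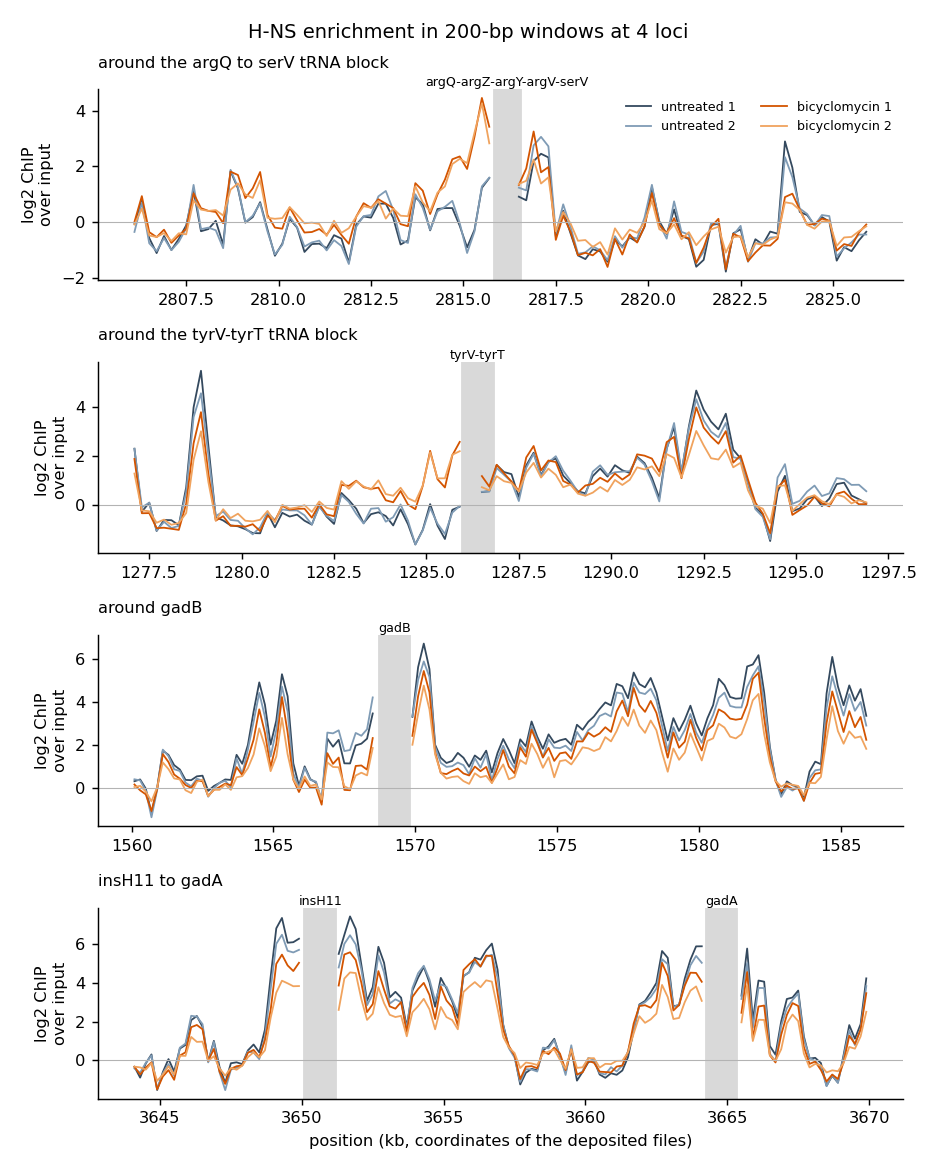
Lines give the log2 ratio of each ChIP library to the mean input of its treatment in 200 bp windows along 4 loci (position in kb), with recognised repeats in grey. Treated libraries lie above untreated ones to the left of the argQ to serV and tyrV-tyrT tRNA blocks, and mostly below them around gadB and from insH11 to gadA.

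Bound regions were fewer and shorter in sum after bicyclomycin. In 200 bp windows, 864 regions with a summed length of 1036.6 kb (22.3% of the chromosome) were at least 2-fold over input in each untreated ChIP library, against 659 regions of 842 kb (18.1%) in treated cells. Of these, 270 untreated and 47 treated regions overlapped none of the other treatment. Both kinds had a median length of 0.4 kb, the shortest length that could be called, against 1 kb for shared regions. The untreated number was 159 without untreated input replicate 1, the treated number was 88 without treated ChIP replicate 2, and with scaling by total reads they were 17 and 115. Regions of at least 5 kb numbered 23 in untreated and 13 in treated cells. The region at 3794801 to 3806600 was 11.8 kb long in both. Within the untreated region from 1569801 to 1582600, beside gadB on the side of pqqL, the longest treated region began at 1573601. Within that from 1207001 to 1220400 it began at 1213201. The parts before these starts were not free of H-NS in treated cells. There the treated log2 enrichment was 2.83 in the 1 kb window at 1570001 and 5.29 in that at 1211001. The region at 1285001 to 1286000, which ends beside tyrV-tyrT, was found in treated cells and not in untreated cells. No test was made of these counts, and their order turned with scaling by total reads, with 466 untreated regions of 580.6 kb against 554 treated regions of 678 kb.

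In input DNA, the background of the ChIP, no window passed the limma test of treated against untreated cells (0 higher, 0 lower, smallest adjusted p = 0.999). At an unadjusted p under 0.05, 33 were higher and 8 lower, fewer than chance alone would give among 4484 windows. The fit shares its spread between ChIP and input libraries, so the lack of calls does not show that the inputs are equal. Read density declined from an origin placed at 3950000 to the opposite point at 1630162. The ratio of the fitted levels was 1.91 ± 0.0825 (SD, n = 2) in untreated and 2.12 ± 0.217 (SD, n = 2) in treated cells. Its values were 1.96 and 1.85 in untreated replicates 1 and 2 and 1.97 and 2.28 in treated replicates 1 and 2. No test was made of this ratio.

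Levels of prophage stretches in input DNA were measured relative to the replication line, and they are not copy numbers alone, since bound windows took fewer input reads than their share of the windows. In CP4-6, the stretch from insB2 to insB3 was at 1.88 ± 0.266 (SD, n = 2) in untreated and 1.71 ± 0.688 (SD, n = 2) in treated cells, and that from insH1 to insB2 at 1.40 and 1.29. The CP4-6 stretches from thrW to insN-insI1 and from there to insH1 held almost no uniquely placed reads, at 0.000104 or less in both treatments. The emrE to nmpC part of DLP12 was at 0.455 ± 0.257 (SD, n = 2) and 0.341 ± 0.0757 (SD, n = 2); the untreated level was 0.637 without untreated input replicate 1 and 0.273 without untreated input replicate 2. Its part from insH2 to insL2 was at 1.02 and 0.959. The Rac stretch was at 0.957 and 1.00, the Qin stretch at 0.775 and 0.820, and the CP4-57 stretch at 0.913 and 0.859, each with genes outside the prophage list.

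**Figure D5:**
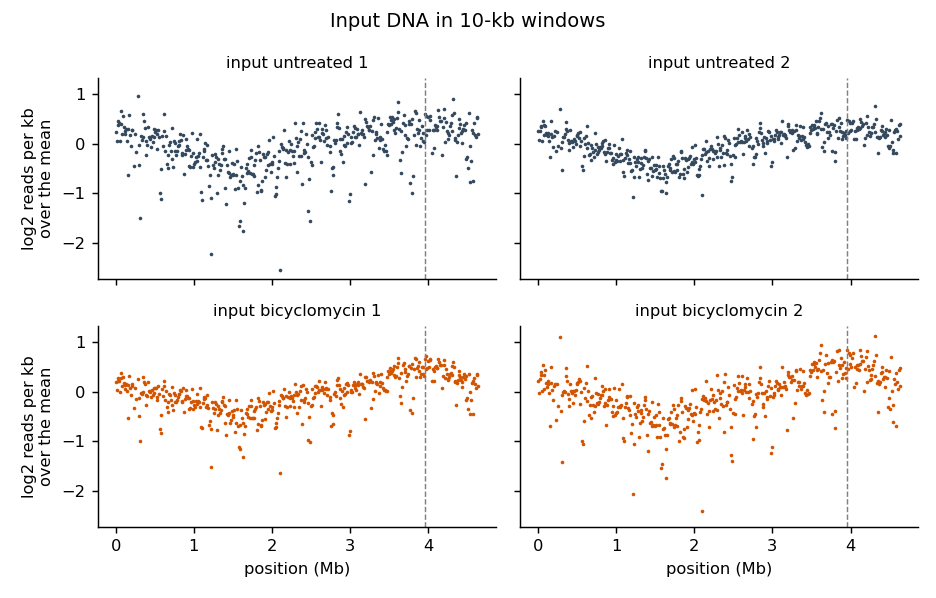
Points give the log2 of input reads per kb over the library mean in 10 kb windows along the chromosome (position in Mb) for the 4 input libraries, and the dashed line marks the origin estimate at 3950000. Density is highest near the origin and lowest near the opposite point, with fitted ratios from 1.85 to 2.28.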

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

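The tests of background DNA for the common fall and for the rises, of duplicate reads for the fall, and of bicyclomycin for the input shares were chosen only after the result had been seen. Enrichment of ChIP over input differed between treated and untreated cells, by a test of the difference itself, in 74 windows that were higher and 8 that were lower after bicyclomycin. Among the windows left out as repeats, 38 additional windows were called bound in untreated cells, a signal over input in windows that enter only the alternative without a filter on repeats.

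The lower enrichment of bound windows after bicyclomycin had a median of -0.95. Duplicate reads beyond 10 per position and strand are argued against as the source of the whole fall by a median of -0.81 with that cap. The cap lowered the mean share of ChIP reads in bound windows from 64.4% to 54.7% (untreated) and from 41.2% to 38.4% (treated). A part of the fall from duplicates, and duplicates under the cap, are therefore not excluded. Loss of input reads is argued against by a median of -1.01 with the ChIP libraries alone. For departures of single windows from a common fall, a larger share of background DNA with the input profile in treated ChIP libraries is argued against. Pairs of 1 treated and 1 untreated library scattered around the mixture curve at least 2.28 times as much as pairs of 1 treatment (SD 0.515 to 0.613 against 0.148 to 0.226). For the common part of the fall, background DNA and a loss of H-NS from DNA cannot be told apart, because the fitted shares within a treatment (0.677 and 0.569) and between treatments (0.220 to 0.586) overlap by 0.0167 and no measure of immunoprecipitated amount is among the data. The growth stage at harvest, which the labels do not give for treated cells, stays open and was not tested.

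The rises, strongest beside the argQ to serV, glyV-glyX-glyY and tyrV-tyrT tRNA genes, had a median of 1.14. Fewer input reads are argued against by a median of 1.10 with the ChIP libraries alone. Of the windows, 0% had under 95% of reads at a mapping quality of at least 20. The filter on repeats fixed much of that value, so it decides little about reads shared between repeat copies. With only reads of a mapping quality of at least 20, the same 74 windows were called higher, with a median of 1.14. That result argues against shared reads as the source of these rises. Background DNA with the profile of the input moves enrichment towards 0 and not past it. Yet 65 of the 74 windows (87.8%) lay above 0 in treated cells at an adjusted p under 0.05 (limma). These windows were called higher with the same libraries, which favours that outcome. No ChIP library without the tag is among the data, so background with another profile was not tested. Library batch, sequence composition and growth stage were not tested, since the labels give no batch, no genome of the build was at hand and the harvest stage of treated cells is not stated. A gain of H-NS at these sites under bicyclomycin is therefore a hypothesis.

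The 4 inputs differed in the share of reads in bound windows, from 10.9% to 15.8%, in a way that crossed the treatments. The ranges of the treatments overlapped by 2.37 percentage points, which restates the pattern and with 2 inputs per treatment decides nothing about bicyclomycin, which stays open. Duplicate reads outside bound windows, beyond 10 per position and strand, are argued against, since 97.2% of the range (4.88 points) stayed with that cap. Sequence composition was not tested, for lack of a genome of the build, and stays open.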

How the results depend on the processing

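The crossed replicate block, shifted windows, 2 kb windows and the omission of both inputs with few reads in bound windows were chosen after the result was seen. With 2 libraries a group, the simulated 1.5-fold changes were recovered in 22% of windows and 2-fold changes in 86%, so many small changes of single windows would be missed. The simulation gave all windows of a group the same spread and drew them independently. In bound windows ChIP replicates differed by a median of 0.447 (untreated) and 0.543 (treated) log2, against 0.121 and 0.188 over all windows. The simulated rates therefore do not hold for bound windows, where larger changes can also be missed. The 10 most enriched windows had larger changes and were not called. The median change of bound windows stayed negative under every setting run, from -1.26 to -0.65 without 1 library, at -0.15 with quantile normalisation and at -0.82 without both inputs with few reads in bound windows. Its camera p with an estimated correlation ranged from 0.0368 (total reads) to 0.552 (quantile normalisation). In all settings run on the same 1 kb windows, the 74 rises stayed positive, and the 8 falls stayed negative except 1 with scaling by total reads. For the values that follow the cause was not tested, except that leaving out a library leaves fewer samples.

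Scaling by total reads gave 654 windows bound in untreated cells, 1614 higher and 72 lower windows, and 466 untreated regions of 580.6 kb. Quantile normalisation gave 279 higher and 237 lower windows. Voom weights gave 600 windows bound in treated cells and 0 higher and 0 lower windows. Keeping at most 10 reads per position gave 2 lower windows and 54.7% of untreated ChIP reads in bound windows. The replicate block gave 13 higher and 0 lower windows, the block within treatment 12 and 2, the ChIP libraries alone 725 and 927, the crossed block 457 and 922, and the omission of both inputs 127 and 59. Without 1 library the higher windows ranged from 0 to 79 and the lower from 0 to 86. The untreated origin ratio was 1.77 from medians within 250 kb. The untreated input level of insE3-insF3 to insH2, with emrE, was 0.637 and 0.273 without untreated input replicates 1 and 2. Relative to the flanking 50 kb, input levels in untreated and treated cells were 0.922 and 0.920 for Rac and 0.957 and 0.924 for insH2 to insL2. They were 0.799 for the CP4-57 stretch in untreated cells and 1.46 for insH1 to insB2 in treated cells.

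Of 46 named windows and stretches under all settings, 818 values kept direction and side of the threshold, 174 lost the call, 44 gained it and 22 turned sign, counting windows under scaling by total reads without correction for its common shift. With quantile normalisation the change turned to 0.14 (568001, emrE), 0.40 (3186001, yqiH), 0.48 (3365001, yhcF), 0.35 (3652001, slp), 0.83 (3663001, gadX), 0.39 (insH11 to gadA), 0.037 (insE3-insF3 to insH2) and 0.0046 (CP4-57). That setting takes out a common fall, so these turns are relative to that fall. With scaling by total reads, where the median of all windows was 0.63, it was 0.044 (575001, essD) and 0.46 (3365001); relative to that median these were -0.58 and -0.17, with no turn, and the ETT2 stretch turned to 0.015. The ETT2 stretch also turned to 0.0010 without the repeat filter, 5.5e-05 with 5-prime ends and 0.0096 without both inputs, and ranged from -0.034 to 0.0071 without 1 library. The ygeP window (2996001) turned to -0.0064 with at most 10 reads per position and ranged from -0.25 to 0.81 without 1 library. The yhcF window was 0.054 without both inputs and ranged from -0.49 to 0.13 without 1 library.

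The differences between replicates 1 and 2 correlated across 4484 windows, which are not independent, at 0.664 between untreated and treated ChIP and 0.794 between treated ChIP and its input. They correlated at -0.579 between untreated ChIP and its input and at -0.868 between treated ChIP and untreated input. The numbers of the untreated inputs may not match those of the other groups, which the labels do not settle. If the numbering within groups is arbitrary, a group with opposite signs can arise from the numbering alone, so the correlations do not settle it either. With these numbers exchanged in the block, 922 windows were lower, 693 of them bound. That exchange was chosen from the same correlations, so its counts do not decide whether the numbers match.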

Other observations

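The tests of nearness to tRNA genes and of the downstream side of tRNA operons were chosen only after the result had been seen. Of 114 windows beside matched repeats, 47 were bound in the average of both treatments, where 21.9% of all tested windows were, and 5 changed past the threshold. By kind, 32 of 60 windows beside insertion elements were bound, 5 of 26 beside tRNA genes and 1 of 14 beside ribosomal RNA operons; no test was made of these counts. Among windows chosen for high values, the window on the yhiS side of insH11 had a log2 enrichment of 6.47 in untreated and 4.54 in treated cells, and that on the yhhH side of rhsB 6.16 and 4.20. The window on the yibA side of rhsA had 5.56 and 3.77, and that on the pqqL side of gadB 4.58 and 2.83. None of these 4 differences passed the limma test.

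Beside tRNA genes the changes were unequal. On the nac side of asnV, the window next to the block had 1.02 untreated and 2.26 treated (adjusted p = 0.0537 by limma), and on the yjjZ side of leuV-leuP-leuQ 0.88 and 1.80 (adjusted p = 0.113). On the xapR side of valU the order was opposite, with 2.86 and 1.59 (adjusted p = 0.169). The windows on the orn side of glyV-glyX-glyY and on the purU side of tyrV-tyrT changed by 0.01 and 0.02.

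A stretch of 14.6 kb from 259601 to 274200, which starts on the proA side of thrW and runs through part of the CP4-6 prophage into insH1, held 76 reads with a mapping quality of at least 20 in all 8 libraries together. That is 0.0162% of the median density of 32145 reads per kb. Reads of any mapping quality numbered 62095 there. Genes there by order in the gene table include ykfI, yafW, perR and ykfC, and the cause was not tested.

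One hypothesis is that rises after bicyclomycin lie near tRNA genes. Of the 13 matched tRNA blocks with a tested window within 2 kb, which leaves out thrW, 5 had a higher window within 2 kb, where 4638 rotations of the calls around the chromosome gave a mean of 0.842 and a highest of 6 (adjusted rotation permutation p = 0.00711). With the calls of quantile normalisation it was 7 of 13 blocks (adjusted rotation permutation p = 0.0317). Insertion elements (2 of 31 blocks, without insN-insI1 for the same reason, adjusted permutation p = 0.988) had about the rotation mean of 2.27. For ribosomal RNA operons (0 of 7 blocks, adjusted permutation p = 1) the rotation mean was 0.80, so the test cannot show a lack of nearness. Rotated calls could also fall on untested windows inside blocks, which raises the rotation counts. Since the pattern was seen before it was tested, a link to tRNA genes may be a property of these calls alone, and the calls themselves end with voom weights.

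A further hypothesis, that the rise lies on the downstream side of tRNA operons, was left open. Over 9 operons with several genes the change was higher downstream in 5, with a mean difference of 0.53 (SD 1.17), and the two-sided exact sign-flip permutation test gave p = 0.246. The windows downstream of glyV-glyX-glyY, argQ to serV and tyrV-tyrT were higher than those upstream by 2.34, 1.96 and 1.28, and that downstream of valU differed by -1.34.

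A last hypothesis was that bound windows lose H-NS unequally at the borders and inside of bound regions. The median departure from the common fall was lower inside than at the border in each of the 4 pairs of 1 treated and 1 untreated library, but only by -0.0497 in the pair nearest to 0 and -0.110 in the farthest, over 324 windows inside and 659 at borders. Windows without a bound window on both sides counted as border, which includes isolated bound windows. The windows of 1 kb also exceeded the median region length of 0.8 kb. The comparison therefore cannot separate the borders of short regions from their insides, and position within a region stays open.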
